A study of Homo sapiens with 4 samples.

How the data were processed

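Total RNA of KYSE410 cells, a line of oesophageal squamous cell carcinoma, was measured in 4 conditions with 1 array each: control and 10 µM defactinib at 4 h and at 24 h. Per the labels, 0.5 µg of RNA was amplified and labelled with Cy3 in 1 colour. Images were extracted with Agilent Feature Extraction 10.7.1.1. Per the file headers, the processed signal of each deposited scanner file is a spot intensity on a linear scale with background subtraction and detrending and no normalization between arrays. The deposited value table holds log2 values that the authors had quantile normalized, since its 4 columns hold identical sorted values and each keeps the rank order of its own scanner file. How the authors made that table is not stated in the labels. The scanner files were the main source and the deposited table an alternative. Group and time were taken from the labels, and array and group cannot be told apart with 1 array per group. All 4 arrays lay on 1 slide, at positions 1 to 4, and no batch could be separated.

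Spots marked as non-uniform or as population outliers were left out, 111, 91, 88 and 148 of 60901 spots on the control 4 h, defactinib 4 h, control 24 h and defactinib 24 h arrays, and no spot was saturated. Replicate spots of a probe were averaged on the log2 scale. Their median standard deviation within an array was between 0.03 and 0.05 log2 units, which is the error of the array and not that of the cells. The 75th percentile of the processed signal over all probes was 269.6, 70.1, 366 and 40.3 on these arrays, in the same order. Probes were assigned to genes by symbol (31127 probes), accession (3343) or synonym (496) using the RefSeq annotation, and 23235 probes without a gene name were left out of the gene results. Probe positions are those printed in the scanner files on hg19. A gene is 1 symbol, with the value of its probe of highest mean signal over the 4 arrays, and 8204 genes had several probes.

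Log2 processed signals were scaled by subtracting the 75th percentile of each array over probes well above background on all 4 arrays, because under 50% of the probes reached that level on the defactinib arrays. Well above background is the call of the extraction software, and the dimmest such probe had a signal between 9.70 and 10.5 on the 4 arrays. Values of a gene or list are log2 ratios minus the median ratio of all genes well above background on both arrays of the comparison. A gene detected on 1 of the 2 arrays is given as a bound, with the undetected array at its lowest well-above-background signal or at the gene's own signal where that was higher. Genes at least 2-fold different were counted for each time and between the controls. The shared change was tested with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3 over 13595 genes, with treatment and time as additive terms and 1 residual degree of freedom. The prior had 9.03 degrees of freedom and a standard deviation of 0.44. In this fit the times act as replicates, so a difference between times counts as error. A gene rose or fell where it also passed, with the same sign, when each defactinib to control ratio was centred on its median. Shared changes are given relative to the median gene, while their standard errors and adjusted p-values are those of the fit before this centring. Tested on simulated data, the fit recovered 3 of 50 genes changed by a log2 of 1, 41 of 50 at 2, 49 of 50 at 3 and 50 of 50 at 4, with 39 false calls among the other genes. These false calls were a larger share of all calls than the threshold of 0.05 aims at. With 50% of the genes changed by a log2 of 2, 94.9% of these were recovered and 2.49% of the calls were false. The simulated noise was independent between genes, with no difference between times and no trend with GC or brightness, unlike these arrays.

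Before the data were examined, 37 gene lists of 729 genes, 720 of them on the array, were fixed for a squamous carcinoma line given a FAK inhibitor, with markers of other cell types as a check, together with the tests and most alternatives. The median ratio of each list was placed among 10000 random lists of the same size matched on mean signal in 20 bins, and a list was called outside their central 95%. This percentile describes the arrays and is not a test over replicates, and 36 lists had enough members at both times, which makes 72 list medians. Tested on simulated lists, 6 of 100 were called with no shift, 55 of 100 with a shift of 0.5 and 98 of 100 with a shift of 1.

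Named genes followed a rule fixed before the data were examined. It took the 10 highest and 10 lowest ratios at each time among genes at least 2-fold different in the main setting and after normexp, with all detected probes in 1 direction. It further took the 10 highest and 10 lowest shared changes, up to 4 members of each list called or with 3 or more members at least 2-fold different, 5 genes lost and 5 gained at each time, the 5 largest differences between times in each direction, and 10 fixed genes. Names that are only a locus number, clone or accession were not used. Any other named gene is said to have been chosen after its values were seen.

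The alternatives planned in advance were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization alone, median centring, the deposited values, the median of a gene's probes, other filters on dim genes, thresholds of 1.5-fold and 3-fold, an adjusted p under 0.1, a trended and robust prior, no term for time, and leaving out each array. Chosen after the data were seen were the 75th percentile over all probes, scaling to 8 spike-in probes, no scaling, centring of the ratios and removal of the trend with probe GC by lowess (fraction 0.3). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest. Left out were control spots other than the spike-in probes and any test of a single time point or of the difference between times, for which the design leaves no residual degrees of freedom.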

Results

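Gene expression was measured in KYSE410, an established line of human oesophageal squamous cell carcinoma, grown with or without 10 µM defactinib for 4 h or 24 h. Defactinib is a small-molecule inhibitor of focal adhesion kinase (FAK, encoded by PTK2) and of its relative PYK2 (PTK2B), kinases that relay signals from integrins at cell contacts with the matrix. The stated purpose of the series was to screen for genes whose expression the drug affects. Total RNA from each of the 4 conditions was labelled with Cy3 and hybridized to 1 one-colour Agilent array, so the design holds 1 array per group and no replicates. The 4 arrays lay on 1 slide. Each carried 58201 distinct probes, of which 34966 could be assigned to 23548 named genes. As the depth of each array, the 75th percentile of the processed signal was 269.6 in the 4 h control, 70.1 with defactinib at 4 h, 366 in the 24 h control and 40.3 with defactinib at 24 h. Probes well above background made up 60.1% of all probes in the 4 h control, 44.2% with defactinib at 4 h, 64.5% in the 24 h control and 43.7% with defactinib at 24 h. The number of arrays limits the precision of every value given here.

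Both defactinib arrays were dimmer than their controls across most genes. Without any scaling, the median gene had a log2 ratio of defactinib to control of -1.72 at 4 h and -2.99 at 24 h, whereas the 24 h control differed from the 4 h control by 0.23. RNA spiked in at known amounts did not share this loss: the mean over 8 spike-in probes was higher with defactinib by 0.57 log2 units at 4 h and by 0.02 at 24 h. At 4 h, 2964 genes were well above background in the control and not with defactinib, and 73 genes were so with defactinib alone. At 24 h the corresponding numbers were 4130 and 192, and 2058 genes were lost and 11 gained at both times. The 100 brightest probes carried 18.8% of the signal in the 4 h control and 27.2% with defactinib at 4 h. At 24 h their share was 17.1% in the control and 32% with the drug. Because of this shared loss, gene and list values below are log2 ratios relative to the median gene of the same comparison, and a gene described as higher can still have had a lower signal with the drug. On the scaling used for counting genes (each array set to its 75th percentile), the median gene lay at 0.23 at 4 h and 0.26 at 24 h.

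**Figure D1:**
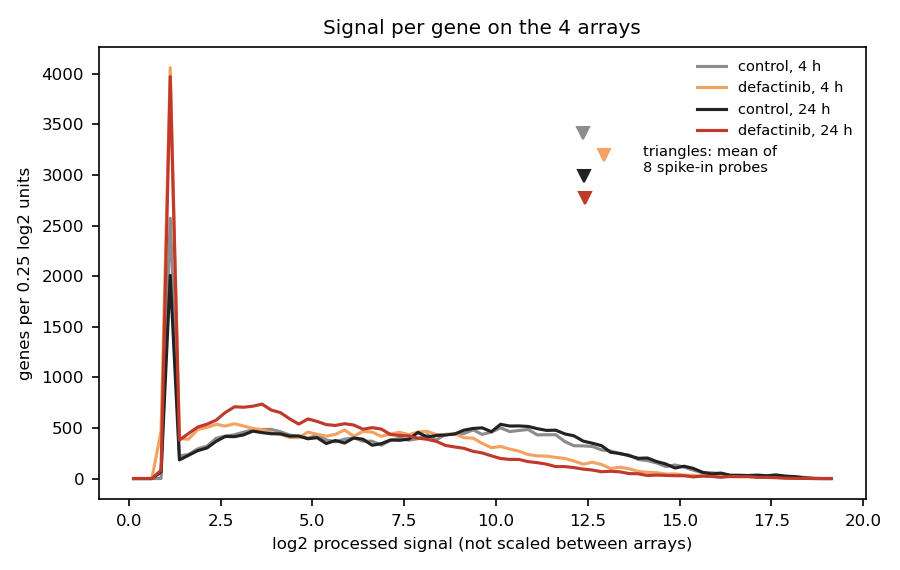
Number of genes (vertical axis, per 0.25 log2 units) at each log2 processed signal (horizontal axis, not scaled between arrays) on the 4 arrays, with triangles at the mean of 8 spike-in probes. Both defactinib arrays hold fewer genes at high signal than their controls, while their spike-in means, 12.95 at 4 h and 12.42 at 24 h, are not below those of the controls, 12.38 and 12.40.

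At 4 h, genes of MAPK pathway output and immediate early genes were far below the median gene with defactinib. MYC, a transcription factor that drives growth, went from a signal of 43440 to 280.7, a relative log2 ratio of -5.56. The feedback regulators of the ERK pathway DUSP6 and SPRY2 had ratios of -4.33 and -4.43, and the early-response transcription factor KLF10 had -4.79. CCN1 and NUAK2, targets of the YAP/TEAD transcription factors, had -5.15 and -5.62. DKK1, a secreted Wnt antagonist, was the lowest of the named genes at -7.23, followed by the polo-like kinase PLK2 at -6.15. The cytosolic ribosomal proteins stood highest as a group, with a median of 1.22.

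The 4 h comparison asked which genes respond early to the drug. Of 14781 genes well above background on both arrays, 2745 were at least 2-fold higher with defactinib and 2123 at least 2-fold lower after scaling to the 75th percentile. Other genes with the lowest relative ratios were HPS6 at -5.79, FADD, an adaptor of death receptors, at -5.73, the kinase SGK1 at -5.63, RPUSD2 at -5.56, the vasodilator peptide gene ADM at -5.51, TRIB1 at -5.45 and the Wnt receptor FZD10 at -5.40. At the upper end, the long non-coding RNA LETR1 had 5.39, the pseudogene HERC2P4 4.42, CASC15 4.35, the vesicular GABA transporter SLC32A1 4.27, SGCD 4.16, the T cell co-stimulator CD86 4.16 and GABRA3 4.08. Also at this end were DHTKD1 at 5.43 and LHFPL6 at 5.28, and LASP1NB had 14.66, a value that rests on a single bright spot of 1 array. DHTKD1 and LHFPL6 were each read by 1 probe, with signals of 21540 and 39430 on the 4 h defactinib array. On the 4 h control, 24 h control and 24 h defactinib arrays, DHTKD1 had 1639, 2887 and 338.4. LHFPL6 had 3330, 2233 and 97.6 there. Among genes lost from detection, LCMT2 was at least 44.3-fold lower relative to the median gene, HYMAI at least 43.3-fold, BCAR3, which binds the FAK substrate p130Cas, at least 36.5-fold, EBLN2 at least 36.3-fold and CLP1 at least 33.1-fold. Among genes gained, SLC6A17 was at least 8.03-fold higher, IGFALS at least 6.83-fold, TSPYL5 at least 6.66-fold, CYP8B1 at least 6.45-fold and ADGRE3 at least 6.40-fold. None of these 4 h values carries a test, since each group had 1 array. The division into higher and lower moved with the scaling: it was 868 and 1621 genes after normexp background correction with quantile normalization, 1931 and 2169 after quantile normalization, 1913 and 2173 on the deposited values, 3710 and 1751 after median centring, 1756 and 2711 after centring of the ratios, 32 and 13818 after scaling to the spike-in probes, and 68 and 11776 with no scaling.

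Of 36 gene lists with enough measured members, 12 had a median outside the central 95% of matched random lists at 4 h. MAPK pathway output had a median of -2.47, or -1.72 with its 3 lost members at their bounds, with 6 of 11 measured members at least 2-fold below the median gene, among them the ERK pathway inhibitors SPRED2 at -3.03 and SPRED1 at -2.60. Immediate early genes had a median of -2.04, and 11 of 20 lay at least 2-fold below, MYC and KLF10 furthest, while FOS was at 0.87 and EGR2 at 0.26. Genes repressed by PI3K through FOXO had a median of -1.84, where the cell-cycle inhibitor CDKN1B stood at -3.86, the stress-response gene GADD45B at -3.62 and TXNIP, an inhibitor of thioredoxin, at -3.44. YAP/TEAD targets had a median of -1.19, with FJX1 at -4.14 and AMOTL2 at -3.23 besides CCN1 and NUAK2. Wnt and Notch targets were also at -1.19, with the Notch ligand JAG1 at -2.01, the Notch target NRARP at -1.98 and the Wnt inhibitor RNF43 at -1.44. Aryl hydrocarbon receptor targets had a median of -0.97, with TIPARP at -4.61 and CYP1A1, a xenobiotic-metabolizing enzyme, at -1.88. Ribosome biogenesis genes had a median of -0.77, with the RNA polymerase I subunit POLR1C at -3.46 and NOP16 at -1.88. G2 and mitosis genes had a median of -0.56, with the mitotic kinase AURKA at -2.43 and CKS2, a partner of cyclin-dependent kinases, at -1.94. FAK and focal adhesion adaptors had a median of -0.49, with TNS4 at -3.70 and the adaptor CRKL at -3.19. S phase genes had a median of -0.38, with cyclin CCNE2 at -2.45, and cytosolic heat shock proteins one of -0.32, with DNAJB1 at -4.04. Of the 28 cytosolic ribosomal proteins, 22 lay at least 2-fold above the median gene, among them RPS2 at 1.62 and RPL12 at 1.44, although quantile normalization brought the list median to 0.05, inside the range of matched lists, and the deposited values gave -0.01. Removal of the trend with probe GC content brought the FAK adaptors, the aryl hydrocarbon receptor targets and the heat shock proteins inside the range, the last with a median of 0.03, and the FAK adaptors also lay inside it with normexp and quantile, with no filter and with genes detected on all 4 arrays, as did the aryl hydrocarbon receptor targets with normexp and quantile. In simulated data, 6 of 100 lists with no shift fell outside the range, so single list calls are uncertain.

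At 24 h, immediate early genes lay on both sides of the median gene, whereas most cell-division and interferon genes lay below it. FOS, the early-response transcription factor, reached a relative log2 ratio of 6.84, and EGR2, of the same class, 3.94, while BTG2, of the same list, was at -3.01. CCN1 and KLF10, far below the median gene at 4 h, stood at 3.33 and 2.32. AURKA had a ratio of -3.82, the mitotic motor KIF11 -3.24 and the cyclin-dependent kinase partner CKS2 -3.07. OASL, IFI44L and IFIT1, all induced by interferon, had -4.07, -4.03 and -3.76. SPRR3, SPRR1B and SPRR1A, components of the cornified envelope of squamous cells, had 3.12, 2.86 and 2.74, but the 24 h control stood at -1.21, -2.24 and -1.74 relative to the 4 h control for these 3 genes.

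The 24 h comparison asked which genes differ after prolonged exposure. Of 14284 genes well above background on both arrays, 4265 were at least 2-fold higher and 2996 at least 2-fold lower on the scaled values. Besides FOS, the highest relative ratios were those of WFIKKN2 at 8.19, TOGARAM2 at 6.42, HERC2P4 at 6.35, NSG2 at 6.16, ISLR2 at 6.14, the small nucleolar RNA SNORD95 at 6.08, LETR1 at 6.06, ESPNL at 5.97 and SLC32A1 at 5.88. The lowest were ATXN7L3B at -4.37, the nuclear receptor coactivators PNRC1 and PNRC2, both at -4.25, NUFIP2 at -4.20, DOLK at -4.15, the zinc finger gene ZNF7 at -4.12, ZBED5 and HOMEZ, both at -4.09, FAM53C at -4.07 and OASL. Genes gained from below detection were IFNA22P, at least 214.5-fold higher relative to the median gene, ACTL7B, at least 188.1-fold, TMEM119, at least 175.4-fold, KCNE4, at least 119.8-fold, and PHYHIP, at least 117.2-fold. Each of these was read by 1 probe, with a signal of 12.0 or less on the other arrays, so these folds rest on 1 probe of 1 array. Of the highest ratios, those of WFIKKN2, TOGARAM2 and NSG2 share this limit. Their 24 h control signals were 12.3, 13.1 and 11.65, near the lowest well-above-background signal of that array, 9.96. Neither 4 h array had them well above background. Genes lost were PLPP6, at least 27.2-fold lower, SLC61A1, at least 21.9-fold, and FAM200C and TADA1, both at least 17.0-fold. These values also have no test. The higher and lower counts were 1600 and 2716 with normexp and quantile, 3031 and 3522 with quantile normalization, 3017 and 3530 on the deposited values, 5773 and 2062 with median centring, 119 and 12837 with spike-in scaling, and 120 and 12810 with no scaling.

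At 24 h, 8 lists lay outside the range of matched random lists. Interferon-stimulated genes had a median of -1.81 at 24 h against 0.19 at 4 h, with 18 of 22 measured members at least 2-fold below the median gene, IFIT2 among them at -3.30. G2 and mitosis genes had a median of -1.70, and 22 of 32 were at least 2-fold below, including CENPA, the histone variant of centromeres, at -2.96. FOXO and PI3K-repressed genes had a median of -1.21, with CDKN1B at -2.94 and TXNIP at -1.17, while PIK3IP1, an inhibitor of PI3K, was at 2.83. S phase and replication genes had a median of -0.58, with the replication proteins GINS3 at -2.87, POLE2 at -2.54 and CHAF1A at -2.38. Immediate early genes had a median of 0.47, and 9 of 19 lay at least 2-fold above, while MYC was at -0.20 and BTG2 at -3.01. NF-kB targets and cytokines had a median of 0.70, with the cytokines TNF at 3.26 and CXCL8 at 1.60 and the feedback inhibitor TNFAIP3 at 1.38, while NFKBIA was at -2.09. Squamous differentiation genes had a median of 1.17, and 12 of 19 were at least 2-fold above, with LCE3D, of the late cornified envelope, at 3.62 besides the SPRR genes. PIK3IP1, TNF and LCE3D were dim in the 24 h control, with signals of 31.7, 54.9 and 25.1. With defactinib at 24 h they had 28.5, 66.5 and 39.1. All 28 cytosolic ribosomal proteins lay at least 2-fold above the median gene, with a median of 1.93, but the median was -0.06 after quantile normalization, -0.05 with normexp and quantile and -0.07 on the deposited values. Without scaling the ribosomal protein median was -0.50 at 4 h and -1.05 at 24 h, a smaller loss than that of the median gene. Calls at 24 h that ended were S phase and squamous differentiation with the GC trend removed, immediate early genes after quantile normalization of any kind and with no filter, FOXO targets with the median of probes and with genes detected on all 4 arrays, and NF-kB targets with no filter. The call of the ribosomal proteins as higher at 24 h also ended after quantile normalization of any kind. MAPK pathway output had a median of 0.31, inside the range, which became -0.34 when its undetected members were set to their bounds. Of the other lists called at 4 h alone, Wnt and Notch targets had -0.93 at 24 h, YAP/TEAD targets -0.45, ribosome biogenesis and FAK adaptors both -0.17, and aryl hydrocarbon receptor targets 0.04. The cytosolic heat shock proteins median at 24 h was 0.16, inside the range, and became -0.79, outside it, after quantile normalization. Of the lists called at 24 h alone, NF-kB targets had -0.73 and squamous differentiation -0.01 at 4 h.

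**Figure D2:**
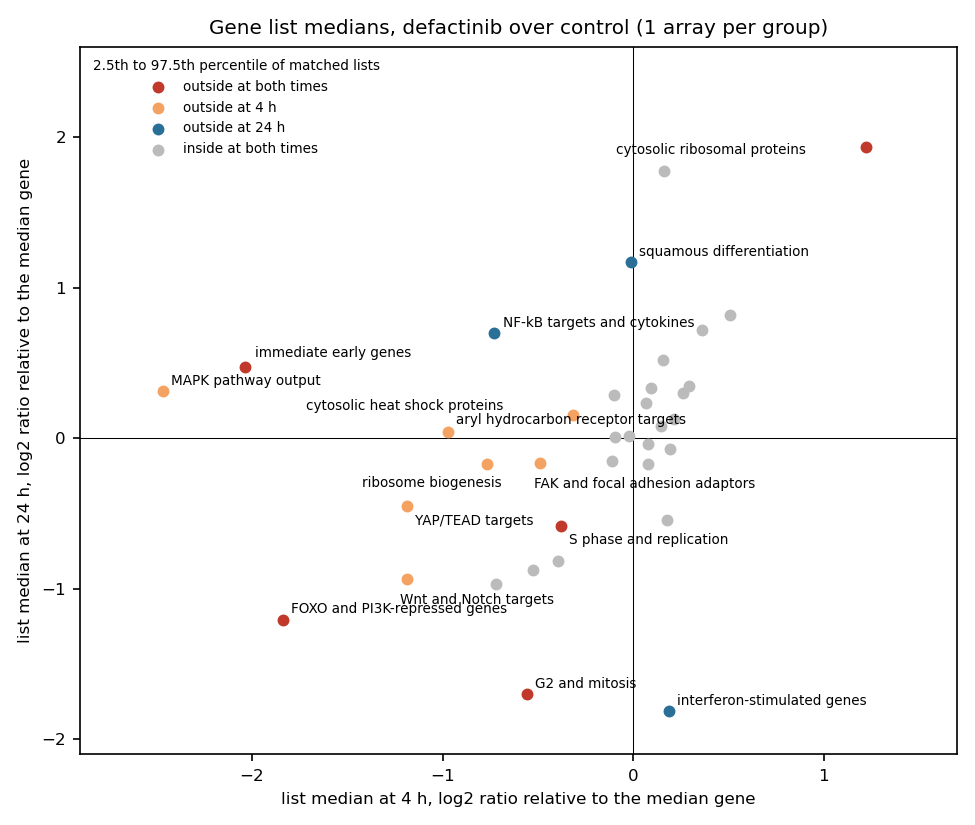
Median log2 ratio of each gene list relative to the median gene at 4 h (horizontal axis) and 24 h (vertical axis), 1 array per group, coloured by whether the median lies outside the central 95% of matched random lists. Immediate early genes lie at -2.04 and 0.47 and interferon-stimulated genes at 0.19 and -1.81. The ribosomal proteins, at 1.22 and 1.93, lie between -0.07 and 0.05 with quantile normalization of any kind.

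**Figure D3:**
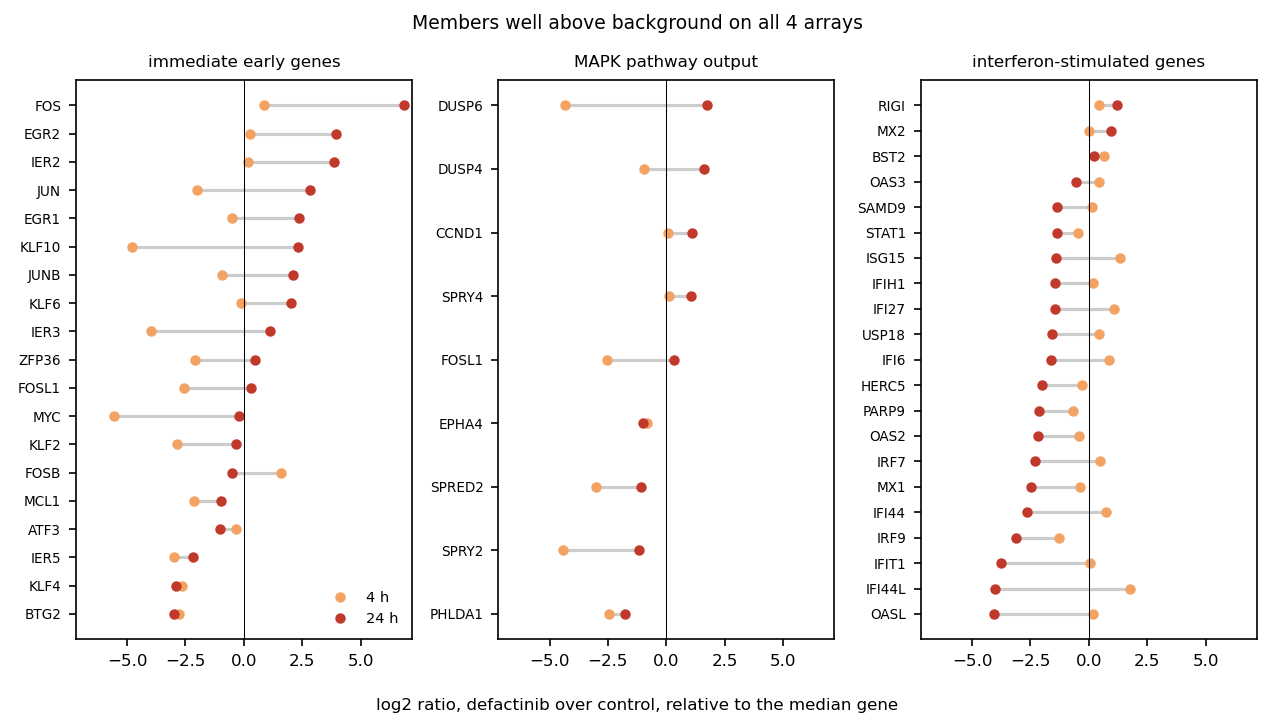
Log2 ratio of defactinib to control relative to the median gene (horizontal axis) for members of 3 lists that were well above background on all 4 arrays, with the 4 h value in orange and the 24 h value in red. Most immediate early genes lie further right at 24 h than at 4 h, as FOS does at 0.87 and 6.84, and most interferon-stimulated genes lie further left, as OASL does at 0.17 and -4.07.

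Changes shared by both times included falls of SOX2, of DKK1 and of 12 of 32 G2 and mitosis genes. SOX2, a lineage transcription factor often amplified in squamous carcinoma, fell by 3.29 on the log2 scale relative to the median gene (standard error 0.48, limma adjusted p = 0.00359). DKK1 (probe at chromosome 10, 54076687 to 54076746, hg19) fell by 5.10 with a standard error of 0.80 (adjusted p = 0.00407). The keratins of basal and activated squamous cells KRT14, KRT16 and KRT17 rose, with KRT14 at 1.88 and 2.70 at the 2 times, and were lower in the 24 h than in the 4 h control, KRT14 at -2.34. PTK2 itself, the target of the drug (probe at chromosome 8, 141669110 to 141669169), did not pass, with -0.83 at 4 h, -0.94 at 24 h and an adjusted p of 0.278. PTK2B, the second kinase that defactinib inhibits, fell by 1.84 (standard error 0.47, adjusted p = 0.0351), a call that ended after quantile normalization and after median centring. Each of these genes that rose or fell showed that direction at both times.

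The shared change was the one comparison with a test, a limma fit over all 4 arrays with time as an additive term, 2 arrays against 2 and 1 residual degree of freedom. It tests the mean change over both times, so a gene can pass on a change at mainly 1 time. Of 13595 genes detected on all 4 arrays, 1809 were higher and 1476 lower at an adjusted p under 0.05, and 5421 passed unadjusted. A gene is said to have risen or fallen where it also passed with the ratios centred on their median, which left 1306 that rose and 1476 that fell. The lowest changes after DKK1 were FADD at -4.85, RPUSD2 at -4.75, ZBED5 at -4.71, FZD10 at -4.68, HPS6 at -4.63, HILPDA, a lipid-droplet protein induced by hypoxia, at -4.51, SGK1 at -4.51, DOLK at -4.46 and HOMEZ at -4.36, all with an adjusted p of 0.00149 or 0.00192. The highest were LETR1 at 5.73 (adjusted p = 0.00104), HERC2P4 at 5.38, SLC32A1 at 5.07, CASC15 at 5.04, SGCD at 4.96, CD86 at 4.86, ESPNL at 4.81, SNAR-E at 4.64, CASC18 at 4.61 and MIEF1, a mitochondrial fission factor, at 4.60, the last with an adjusted p of 0.00169. SLC32A1, SGCD, ESPNL and CASC18 were dim, with signals from 12.0 to 24.1 in the 4 h control and from 11.3 to 21.8 in the 24 h control. Genes this dim could enter the test only if they stayed detected with the drug. FOS rose by 3.85 (standard error 1.03, adjusted p = 0.0206), with 0.87 at 4 h and 6.84 at 24 h. MIEF1 had a shared change of 0.69 and no call when the median of its probes was used. Quantile normalization turned the direction of ACTB, HSPE1 and HSP90AA1, which had passed on the scaled values, though ACTB and HSP90AA1 had not passed with centred ratios and were not called. With it, 38 other named genes that had passed on the scaled values no longer did. Among them were FOS, EGR2, KRT14, KRT17, CDKN2A, PLK2, NUAK2, ADM and SPRY2. With treatment alone, since 3 arrays leave no residual degrees of freedom once time is in the fit, the count was 1994 over all 4 arrays and depended on single arrays: it was 1275 without the 4 h control, 2643 without the 4 h defactinib array, 934 without the 24 h control and 0 without the 24 h defactinib array (3393 with unadjusted p under 0.05). The split was also 905 higher and 1687 lower with normexp and quantile, 465 and 861 with quantile normalization, 475 and 883 on the deposited values, 3008 and 1120 with median centring, 1307 and 1971 with centred ratios, 39 and 12474 with spike-in scaling, and 33 and 10331 with no scaling.

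Over all 13595 genes in the shared test, 1306 rose and 1476 fell, which gives the share to set beside the count of each list. Within the lists, 25 of 28 ribosomal proteins rose in this test, a direction that the quantile-normalized values do not keep, as given above. All 28 passed adjusted over the list alone. Of 32 G2 and mitosis genes 12 fell, 9 with the GC trend removed, among them AURKA, KIF11, CKS2 and CENPA, and 13 passed adjusted over the list alone; removal of the trend ended the call of CENPA (adjusted p = 0.0797). Among 29 S phase genes 7 fell, including GINS3, POLE2 and CCNE2, and 1 rose; 10 passed adjusted over the list alone. With the GC trend removed 3 of the S phase genes fell and 0 rose, and the calls of POLE2 and CCNE2 ended (adjusted p of 0.0823 and 0.0635). The FAK and focal adhesion adaptors had 29 tested members, of which 6 fell and 8 passed adjusted over the list alone. These 6, named after their values were seen, were PTK2B, the kinase SRC, the scaffold BCAR1 (p130Cas) at -2.73 and -3.18, TNS3, whose call ended with the GC trend removed (adjusted p = 0.056), TNS4 at -3.70 and -3.65, and ARHGEF7. Of 24 genes of the ATF4 stress response 7 fell, including DDIT4 at -4.24 and -2.58, DDIT3, TRIB3 and CEBPG. Another 1 rose, and 8 passed adjusted over the list alone. Of 22 ribosome biogenesis genes 6 fell, including POLR1C, RRS1 and NOP16, 1 rose, and 10 passed adjusted over the list alone. Of 11 FOXO and PI3K-repressed genes 5 fell, CDKN1B and TXNIP among them, and 6 passed adjusted over the list alone. Of 19 immediate early genes FOS and EGR2 rose and 3 fell, BTG2 among them, with 8 passing adjusted over the list alone. The rise of EGR2 rests mainly on 24 h, with 0.26 at 4 h and 3.94 at 24 h. Of 24 cholesterol genes 4 fell, including INSIG1, a regulator of sterol synthesis, at -3.25 and -3.04 and SQLE, whose call ended with the GC trend removed (adjusted p = 0.0580). In the endoplasmic reticulum chaperone list 2 of 17 genes fell, about the share over all genes. They were XBP1, a transcription factor of the unfolded protein response, at -3.88 and -3.75, and HERPUD1. Of 14 heat shock proteins DNAJB1 and BAG3 fell and HSPE1 rose, but HSPE1 turned to -0.06 after quantile normalization. The call of BAG3 ended with the GC trend removed (limma adjusted p = 0.0764). In the hypoxia list 4 of 22 fell, ADM, ANKRD37 and SLC2A1 among them, and 4 of 17 p53 targets fell, including BTG2 and FAS. Of 11 TGF-beta targets 3 fell, including ID1 and ID3. The mesenchymal list had 1 fall of 9, that of SNAI2, a repressor of epithelial genes, again about the share over all genes. In the hypoxia list 1 gene rose, and 0 with the GC trend removed. The TGF-beta target CDKN2B rose, with 0.92 at 4 h and 2.62 at 24 h, while its signal was lower with the drug at both times. Among the falls named for these lists, the calls of SLC2A1 and ID1 ended with the GC trend removed (adjusted p of 0.115 and 0.118).

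The ratios of the 2 times resembled each other across genes. HERC2P4, LETR1 and SLC32A1 were among the 10 highest named genes at both times. Of the 13595 genes, 1761 were at least 2-fold higher and 1414 at least 2-fold lower at both times, against 688.8 and 407.3 for independent lists. Only 56 genes were at least 2-fold higher at 4 h and lower at 24 h, and 42 the reverse. Pearson's correlation of the ratios across genes was 0.73, or 0.69 with the GC trend removed, and genes are not independent replicates. Between 24 h and 4 h, 2016 genes had a log2 ratio higher by 1 or more and 1817 lower by 1 or more. The largest increases were those of CCN1, KLF10, IFNA4, EGR4 and DUSP6, and the largest decreases those of LHFPL6, IFI44L, DHTKD1, STON1 and TNFSF10. Those of LHFPL6 and DHTKD1 rest on 1 probe each that was far brighter on the 4 h defactinib array than on the others. No test of the difference between times was possible, because a model with a treatment by time term leaves no residual degrees of freedom. The same-way counts were 550 and 1153 with normexp and quantile, 1107 and 1517 with quantile normalization, 1093 and 1521 on the deposited values, 2608 and 1041 with median centring, 1140 and 1883 with centred ratios, 28 and 12181 with spike-in scaling, and 53 and 10603 with no scaling. The counts of larger and smaller ratios at 24 h were 741 and 1294 with normexp and quantile, 1495 and 2248 with quantile normalization, 1493 and 2251 on the deposited values, 2814 and 1294 with median centring, 619 and 5007 with spike-in scaling, and 234 and 8219 with no scaling.

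The 24 h and 4 h controls gave the scale of difference between arrays of untreated cells. Interferon-stimulated genes were higher in the 24 h control, with a median of 2.27 over 24 members, IFI44L at 5.48, OASL at 5.39 and IFIT1 at 4.57. FOXO and PI3K-repressed genes were higher with a median of 1.07, cholesterol synthesis genes with 0.68, fatty acid synthesis genes with 0.52, p53 targets with 0.38 and hypoxia genes with 0.24. MAPK pathway output was lower with a median of -0.95, including DUSP6 at -3.89, as were YAP/TEAD targets at -0.96, ribosome biogenesis genes at -0.96, matrix proteases at -0.77 and NF-kB targets at -0.75. Also lower were SRF/MRTF targets at -0.50, heat shock proteins at -0.50, basal squamous genes at -0.42, integrins at -0.40, immediate early genes at -0.38, S phase genes at -0.30 and receptor tyrosine kinases and ligands at -0.29. All of these lay outside the central 95% of matched lists. The lists that stood out in the 24 h defactinib comparison thus include ones whose controls differed: the interferon list and the FOXO list were higher in the 24 h control and lower with the drug at 24 h, the NF-kB and immediate early lists were lower in the 24 h control and higher with the drug, and the S phase list was lower in both. Of 17441 genes well above background on both control arrays, 1979 were at least 2-fold higher at 24 h and 678 at least 2-fold lower, so an array pair without the drug already differed at 2657 genes. These counts became 682 and 382 with normexp and quantile, 1504 and 870 with quantile normalization, 1504 and 876 on the deposited values, 1683 and 938 with median centring, 1420 and 1302 with the percentile taken over all probes, 2636 and 421 with spike-in scaling, and 2719 and 401 with no scaling.

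Genes often altered in squamous carcinoma had mixed values. EGFR fell by 1.80 (adjusted p = 0.0309), but the call ended after quantile normalization, median centring or removal of the GC trend, and with the median of its probes the ratio at 4 h was 0.34 and the shared change 0.03. CDKN2A, the cell-cycle inhibitor p16, rose relative to the median gene, with 1.14 at 4 h and 1.87 at 24 h. Its limma adjusted p was 0.0196 on the scaled values and 0.0283 with the ratios centred. The CDKN2A signal was lower with the drug at both times. TP63 had 0.91 at 4 h and 0.30 at 24 h, CCND1 0.05 and 1.08, MET -0.83 and -1.22, FGFR1 0.66 and -0.37, and MYC -5.56 and -0.20. None of these 5 passed, with adjusted p of 0.17, 0.208, 0.196, 0.546 and 0.0671. With the ratios centred on their median, MYC had a limma adjusted p of 0.0397, so it passed that fit alone and was not called.

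The other 21 lists lay inside the range at both times. Receptor tyrosine kinases and ligands had medians of -0.52 at 4 h and -0.88 at 24 h, TGF-beta targets -0.72 and -0.97, and p53 targets -0.39 and -0.82. The ATF4 list had -0.11 and -0.15, cholesterol synthesis 0.18 and -0.54, and hypoxia and glycolysis 0.08 and -0.17. SRF/MRTF targets had 0.51 and 0.82, oxidative phosphorylation 0.36 and 0.72, and matrix proteases 0.16 and 0.52. Replication-dependent histones had 0.29 and 0.35, basal squamous genes 0.26 and 0.30, and endoplasmic reticulum chaperones 0.09 and 0.33. NRF2 targets had -0.10 and 0.29, extracellular matrix and laminins 0.07 and 0.23, and autophagy and lysosome 0.22 and 0.13. Fatty acid synthesis had 0.15 and 0.08, mesenchymal genes 0.19 and -0.07, and the BCL2 family 0.08 and -0.04. Epithelial junctions had -0.10 and 0.01, and integrins -0.02 and 0.01. Leukocyte and endothelial markers, a check for other cell types, had 0.16 and 1.78 over 6 measured members, of which CD3E and CD3D rose in the shared test. Both were dim. The CD3D signal was lower with the drug, from 48.5 to 41.1 at 4 h and from 55.4 to 28.8 at 24 h. That of CD3E went from 25.4 to 30.0 and from 29.8 to 58.0. Fibroblast and stroma markers had too few measured members for a median, 2 at 4 h and 1 at 24 h; between the controls 3 members had a median of 2.07, higher at 24 h and outside the range at percentile 99.6. With the GC trend removed, ATF4 (percentile 0.97) and receptor tyrosine kinases (2.31) moved outside the range at 24 h.

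Ratios also varied with the GC content and the brightness of the probe. Genes with a probe of 55% GC or more had a median of 0.64 at 4 h and 0.87 at 24 h, and those with 35 to 40% had -0.35 and -0.60, while the control arrays gave -0.11 and 0.05 in the same classes. In 10 classes of genes ordered by control signal, class 5 had a median of -0.32 at 4 h and -0.72 at 24 h, and the brightest class had 0.33 and 0.70, which became -0.19 and -0.14 after quantile normalization. The dimmest class, with control signals from 11.6 to 87.2, had 0.71 and 1.67. The dimmest classes could hold only genes that stayed above background with the drug, so their medians carry no information on a loss. High ratios of single dim genes share this limit. The 14 ribosomal proteins between control signals of 148600 and 250100 had a median of 1.19 at 4 h, against 0.81 for 49 other genes equally bright, and of 1.92 against 1.76 at 24 h. With the GC trend removed, 928 of the 1306 genes that rose and 1022 of the 1476 that fell still passed.

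**Figure D4:**
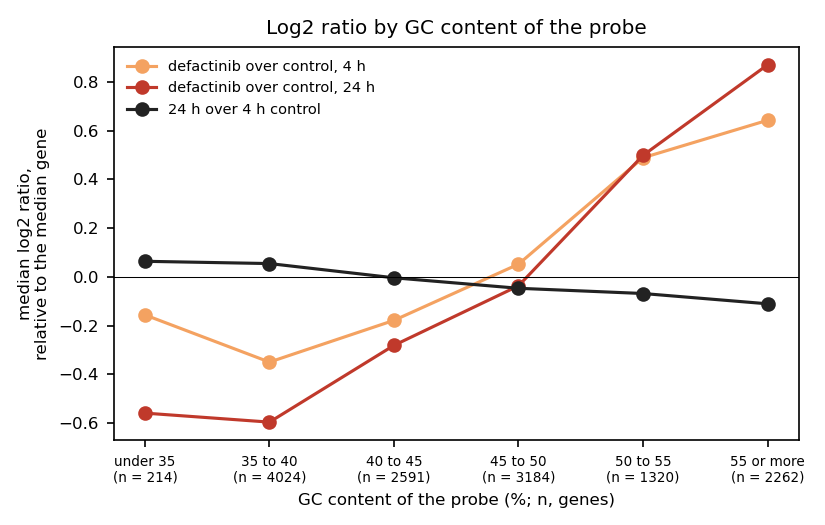
Median log2 ratio relative to the median gene (vertical axis) of genes grouped by the GC content of their probe (horizontal axis, with the number of genes), for defactinib over control at 4 h and 24 h and for the 24 h over the 4 h control. The defactinib medians rise from -0.35 and -0.60 at 35 to 40% GC to 0.64 and 0.87 at 55% or more, and the control medians go from 0.05 to -0.11.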

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

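The tests of the interferon pattern were planned before their results were seen, except that on the quantile-normalized values, which was chosen after, as was the match on control signal in the last paragraph. Every difference between times in this part was found in the values and not tested. All ratios are log2 ratios of defactinib to control relative to the median gene.

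Interferon-stimulated genes were lower with defactinib at 24 h and not at 4 h: IFI44L had 1.75 at 4 h and -4.03 at 24 h, and TNFSF10, also induced by interferon, had 1.95 and -2.87. The tables argue against the GC trend as the source, since the list median at 24 h stayed at percentile 0 of matched lists with that trend removed. A distortion between arrays that depends on signal is argued against by the quantile-normalized values, where the list median nearest to 0 was -1.36, also at percentile 0. What stays open is a difference between the controls: the list was higher in the 24 h than in the 4 h control, with a median of 2.27 at percentile 100, while the 24 h defactinib array differed from the 4 h defactinib array by 0.0769 at percentile 73.8. A candidate explanation is therefore an interferon response that arose in the untreated culture between 4 h and 24 h and not in the treated one. With 1 array per group, a block of that response by the drug and a difference between single cultures stay open, as neither was tested.

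Immediate early genes lay on opposite sides of the median gene at the 2 times, with a median of -2.04 at 4 h and 0.47 at 24 h, the latter turning to -0.091 with no filter on dim genes. Of 19 members measured at 24 h, 9 lay at least 2-fold above the median gene and 4 at least 2-fold below. KLF10, of this list, had -4.79 at 4 h and 2.32 at 24 h. Outside the list, DUSP6, of MAPK output, had -4.33 and 1.74, and CCN1, a YAP/TEAD target, -5.15 and 3.33. EGR4, an early-response transcription factor, had -1.29 and 4.90. The NF-kB targets CXCL8 and TNFAIP3 had -2.31 and 1.60, and -1.36 and 1.38. The interferon alpha gene IFNA4 had -1.18 and 5.31. In the opposite direction, LHFPL6 had 5.28 at 4 h and -1.53 at 24 h, and STON1 1.68 and -3.78. The LHFPL6 value at 4 h rests on 1 probe that was far brighter on the 4 h defactinib array than on the others. The controls of the 2 times differed for several of these: the 24 h control stood at -0.38 relative to the 4 h control for the immediate early list (percentile 0.22 of matched lists), at -0.75 for NF-kB targets (percentile 0), at -3.89 for DUSP6, -3.85 for CXCL8, -3.02 for EGR4, -2.28 for CCN1 and 5.61 for STON1, and for KLF10 at -0.33. No explanation was tested for these differences.

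Probes with no gene name carried signal that the gene results do not use. Of 4637 such probes well above background on all 4 arrays, 1173 (25.3%) were at least 2-fold above the median gene at both times, against 8.41% of the 13595 named genes, and 195 (4.21%) were at least 2-fold below at both times, against 13.9%. The unnamed probes were dimmer, with a median control signal of 149.1 against 1179, and named genes weighted to the control signals of the unnamed probes, in 20 bins, had shares of 16.6% and 6.38%, so the gaps were smaller at equal control signal. What remains of them was not tested. A further 27 unnamed probes were well above background with defactinib at both times and not in the controls.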

How the results depend on the processing

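Spike-in scaling, no scaling, the 75th percentile over all probes, centred ratios and removal of the GC trend were alternatives chosen after the data were seen. Of 99 counts of genes under an alternative, 61 stayed within 1.5 times the count reported and 38 did not. Scaling by 1 factor per array leaves a list median relative to the median gene as it was, so those alternatives say nothing about the lists. Of the 12 lists called at 4 h and the 8 at 24 h, the same call was made for 9 and 6 with normexp and quantile or with the GC trend removed, 11 and 6 with quantile normalization, with the deposited values or with no filter, 12 and 7 with the median of probes, and 11 and 7 with genes detected on all 4 arrays.

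The counts of genes at least 2-fold different at 4 h, at 24 h and the same way at both times were 2489, 4316 and 1703 with normexp and quantile, 13850, 12956 and 12209 with spike-in scaling, and 11844, 12930 and 10656 with no scaling. With no filter on dim genes they were 10220, 14703 and 8115, and at a 3-fold threshold 2028, 4361 and 1232. At a 1.5-fold threshold the 4 h count was 8280 and the count for both times 5721. Between the controls, the count was 1064 with normexp and quantile, 1768 for genes detected on all 4 arrays, 4384 with no filter, 5897 at 1.5-fold and 1052 at 3-fold. Ratios that differed between times numbered 2035 with normexp and quantile, 8453 with no scaling, 7072 with genes detected on at least 1 array, 10319 with no filter, 7173 at 1.5-fold and 1407 at 3-fold. The thresholds and filters move these counts by construction, since they change what is counted or how many genes enter.

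The shared change had 1326 genes with quantile normalization, 1358 on the deposited values, 12513 with spike-in scaling, 10364 with no scaling, 5293 with no filter and 1994 with no term for time. With genes detected on at least 1 array, limma called 0 genes, and 5762 had an unadjusted p under 0.05. With 1 array left out, time cannot be a term as well, so the fit held treatment alone and compares with the 1994 genes above; it assumes the lone array of an arm to vary like the others. It gave from 0 genes without the defactinib 24 h array (3393 with an unadjusted p under 0.05) to 2643 without the defactinib 4 h array, with 1275 without the control 4 h array and 934 without the control 24 h array. The cause was not tested.

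Values that turned are given where the list had been called, the ratio was at least 2-fold or the shared change had passed; smaller and uncalled values are counted. The heat shock protein median at 4 h became 0.035 with the GC trend removed. The ribosomal protein median became -0.014 at 4 h on the deposited values, and at 24 h -0.045 with normexp and quantile, -0.057 with quantile normalization and -0.070 on the deposited values. The immediate early gene median at 24 h became -0.091 with no filter. With normexp and quantile, quantile normalization and the deposited values, in that order, the ACTB log2 ratio at 24 h became -0.13, -0.082 and -0.083. In the same order, the 24 h ratios became -0.061, -0.012 and -0.024 for HSP90AA1, and -0.42, -0.40 and -0.41 for ATP5MC3. The shared changes became -0.25, -0.24 and -0.25 for ACTB, -0.067, -0.064 and -0.079 for HSPE1, and -0.19, -0.18 and -0.20 for HSP90AA1. On the deposited values, RPS2 and RPL12 at 4 h became -0.036 and -0.043. With the median of probes, BCL2L11 at 24 h became -0.84, EGFR at 4 h 0.34 and the shared change of EGFR 0.032. Of all 72 list medians, 351 gene ratios and 162 shared changes, 30, 25 and 7 that were smaller or uncalled changed sign under at least 1 alternative, 11, 13 and 2 of them with the GC trend removed. Among all values of named genes that are not listed as turned, each counted under every alternative, 2143 ratios stayed the same and 1354 moved by more than the spot error. Most of those that stayed did so by construction, since scaling by 1 factor per array cannot move a ratio relative to the median gene. All 351 ratios thus stayed under each such scaling. By contrast, 331 moved with normexp and quantile, 351 with the GC trend removed and 57 with the median of probes. Of the shared changes 1290 kept their side of the threshold, 161 lost it and 159 gained it. The cause was not tested.

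Signal over background limits the dim genes: on the defactinib arrays 44.2% and 43.7% of the probes were well above background, so a gene that dropped out there is given as a bound and genes dim in the control carry no information on a loss.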

Other observations

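The gene classes in the next paragraph and the tests of the signal loss and of the GC trend were chosen after the data were seen, except the test of probe position, which was planned before its result was seen.

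Zinc finger genes named ZNF were low as a class with defactinib. Their median relative to the median gene was -1.40 at 4 h over 330 genes and -1.36 at 24 h over 291, and 0.11 between the controls, and 119 of 274 fell and 8 rose in the shared test. Most encode DNA-binding transcription factors. Small nucleolar RNAs, which guide the modification of ribosomal RNA, were high, with a median of 0.40 at 4 h and 1.59 at 24 h against -0.31 between the controls, and 73 of 199 rose and 5 fell. Long non-coding RNAs had 0.38 and 1.01, and 259 of 1142 rose and 53 fell. At 4 h, 762 of them were lost from detection beside 1298 detected on both arrays, and at 24 h 905 beside 1329, while 24 and 55 were gained. For protein-coding genes the losses were 2025 beside 12842 and 3007 beside 12322. The long non-coding RNA medians thus cover only those that stayed detected, and were 0.25 and 0.66 with the GC trend removed. Keratins had 0.84 and 1.55, and 10 of 29 rose, but they were lower in the 24 h than in the 4 h control, with a median of -0.41 at percentile 0, which bears on their 24 h value. Proteasome subunits had 0.35 and 0.66, inside the range of matched lists. Mitochondrial ribosomal proteins had -0.05 and -0.11, below that range, and were lower between the controls too, with -0.33 at percentile 0.02. With the GC trend removed, the ZNF genes stayed at percentile 0 and the small nucleolar RNAs at percentile 100 at both times, and the other scalings were not run for these classes.

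Both defactinib arrays lost signal while the spike-in RNA kept its own. Less efficient labelling, hybridization or scanning is argued against by the spike-in mean, 0.0196 log2 units higher with defactinib at 24 h where the median gene lay at -2.99. Breakage of the RNA with loss of upstream sequence is argued against as well, since upstream probes kept more signal than downstream probes of the same gene, by a median of 0.71 at 24 h and 0.45 at 4 h. Among probe pairs of similar control signal that median was smaller, 0.51 at 24 h and 0.32 at 4 h. A loss of short-lived transcripts stays open at 4 h. Immediate early genes and MAPK output then lay at or below percentile 0.01 with the GC trend removed. This test was chosen after both lists were seen to be low, and values relative to the median gene do not measure that gene's own fall. Both lists also read the output of signalling, so lower signalling cannot be told apart from a loss of short-lived transcripts. At 24 h such a loss stays open: the higher of the 2 lists lay at percentile 98.8, but members went both ways, with 9 immediate early genes at least 2-fold above the median gene, 4 at least 2-fold below and 3 lost, so this percentile excludes nothing. A smaller share of messenger RNA in the total RNA of treated cells, or less sample RNA taken into labelling, stays open and was not tested.

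Ratios were higher at GC-rich probes in both defactinib comparisons. Probes of the same gene showed this too. Before probe position was allowed for, the slope within genes was 0.85 times the slope across genes at the time where it was lower. A property of the probe or of the labelled RNA is therefore a candidate explanation. GC-rich genes keeping their transcripts are argued against as the whole source, because the slope within genes was 6.59 at 24 h (log2 units per unit of GC fraction, 95% interval 6.15 to 7.05). Probe position is argued against as the whole source too, since with it in the fit the slope at 24 h was 3.90 (3.37 to 4.39). At 4 h it was 2.56, and the slopes across genes were 4.86 at 4 h and 6.57 at 24 h. Among probe pairs of similar control signal, the slopes with position in the fit were 2.26 and 3.02. The share of the trend found within genes was thus smaller once position was allowed for.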
